A study of Mus musculus with 4 samples.

How the data were processed

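RNA from whole testes of 8-week-old male mice was measured on 4 Affymetrix arrays, 2 from wild type and 2 from Taf7l knockout animals, all described as C57BL/6J. The deposited table gives, for each array, a linear intensity (probe set signal) for 45101 probe sets, of which 45037 are for mouse sequences and 64 are controls. The submitters' processing notes name MAS5 for making these signals, with no version and no scaling target, and the normalization stays unsettled. MAS5 treats each array alone and by convention scales it to 1 common trimmed mean. In the table, pairs of arrays share between 4565 and 6142 exact values, the lowest signals lie at 1.72 to 1.73 on all arrays, and the trimmed means (2% cut at each end) were 511 and 511 for wild type and 467 and 483 for the knockout. Wild type replicate 2 and knockout replicate 2 hold the same value at 2385 probe sets, against 229 to 620 for the other pairs. How these shared values arose was not settled, and any fold change below is relative to a scaling that is not given in the sources used here.

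Signals were taken to log2 with an offset of 0 and no further normalization. Probe sets were kept when their mean signal over the 4 arrays was at or above the median of that mean (45.8), which left 22519. Low signals are mostly background, and detection calls were not used here. Genes were named through the platform annotation, with symbols updated through a RefSeq table of assembly GRCm38.p6. Of the mouse probe sets, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed, and 34741 were matched to the RefSeq table. The sources used here name no genome build for the probe sets, so no coordinates are given, and the table served only for names, chromosomes and the order of neighbouring genes. The kept probe sets with 1 symbol numbered 19999 and covered 12241 genes.

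Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the prior variance over mean signal), with genotype as the only term, two-sided, and Benjamini-Hochberg adjustment over the kept probe sets. A probe set was called at an adjusted p under 0.05. The fit had 2 residual degrees of freedom and 3.17 prior degrees of freedom. The number of arrays limits the precision of every value, and an exact permutation test of 2 against 2 cannot go below p = 0.333. Fold changes are differences of mean log2 signal, and means ± SD are of linear signal over 2 arrays. Sizes were also described without a test, by counting probe sets at least 2-fold apart whose groups did not overlap.

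There were 25 gene lists, each written from general knowledge of testis cell types and sperm structures, and 24 had at least 5 measured genes. They were tested with camera from limma at a preset correlation of 0.01, on the brightest kept probe set of each gene, with Benjamini-Hochberg adjustment over the 24 lists. Camera with an estimated correlation and fry were run beside it. Each list's median was also placed among the medians of 10000 random lists of the same size matched on mean signal in 50 bins. Some genes stand on more than 1 list: 15 of the 20 measured genes of the CREM list and 10 of the 21 of the pachytene list are also on another. The list of retrogenes holds genes that are not retrogenes, Dazl among them, and 1 of its entries, Pabpc3, was matched through a synonym to Pabpc6. X-linked genes were compared with autosomal genes by camera and by Fisher's exact test.

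The comparison, the filter, the lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule takes Taf7l, Taf7, Tbp and Fscn1 whatever their values, the 12 called genes with the largest change in each direction, and up to 4 genes with the smallest p on each list. Fscn1 was put there because an account of this mutant was remembered to name it as lower, so its value is not independent evidence. Genes named outside the rule are said to be so. The alternatives were quantile normalization, median centring, an offset of 9.19, no filter, a filter at the 75th percentile, eBayes without a trend and with a robust prior, the replicate number as a block, an adjusted p under 0.10, probe sets for single transcripts, 1 probe set per gene, and leaving out each array in turn. When 1 array is left out, the lone array of its group is assumed to vary like the other group.

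The procedure was tested on simulated data for this comparison, in 10 runs over 22519 probe sets with 200 changed in each. It recovered 5.0% of changes of 0.5 on the log2 scale, 65.4% of changes of 1, 87.0% of 1.5 and 89.0% of 2, counting planted probe sets that fell under the filter as missed, and 5.52% of its calls were false. In a simulation of 24 lists drawn from 12236 genes, 6 of them shifted by 0.2, camera with the preset correlation called 6 of the shifted lists and 0 of the others, fry called 4, and camera with an estimated correlation called 0. Both simulations let probe sets vary independently around limma's own variance trend. The share of false calls rests on that model, and lists whose genes vary together were not simulated. Estimated correlations of the lists called in the results ran from −0.04 to 0.26.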

Results

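The series compared testes of adult mice lacking Taf7l with testes of wild type mice, which the series design describes as littermates, and asked which transcripts differ in the mutant. Taf7l is an X-linked, germ cell-enriched relative of the TFIID subunit Taf7. Each genotype was represented by 2 arrays. The median mouse probe set signal was 45.3 and 45.2 on the wild type arrays and 45.3 and 45.7 on the knockout arrays. The second knockout array is numbered 2 in its title and 1 in its description, and its values differed from those of the first (SD of the log2 difference 0.212) as much as the 2 wild type arrays differed from each other (0.211). Whether the 2 knockout arrays came from separate animals is therefore not settled by the labels, and p-values measure the spread between these arrays, which may be technical.

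Taf7l itself had a signal of 829 and 818 on the wild type arrays and 80.6 and 72.5 on the knockout arrays. Its mean fell from 824 ± 8.06 to 76.6 ± 5.69 (SD, n = 2 each), which is 10.8-fold lower (log2 −3.43, SE 0.097, limma adjusted p = 0.0033). The position of the probe set relative to the deleted part of the gene is not given in the sources used here, so the drop bears on the labels only as far as the probes lie in affected sequence. The paralogue Taf7 was not called, at 392 ± 19.6 and 345 ± 45.2 (adjusted p = 0.39), nor was the TATA-binding protein gene Tbp, at 3526 ± 303 and 3307 ± 13.4 (adjusted p = 0.54), whose difference of −0.09 became 0.05 under quantile normalization. The second kept Taf7 probe set, at −0.15, became 0.01 without knockout replicate 1. With any 1 array left out, the Taf7l change stayed between −3.51 and −3.35 but no longer passed limma's adjustment, with adjusted p of 0.353 without wild type replicate 1, 0.297 without wild type replicate 2, 0.123 without knockout replicate 1 and 0.057 without knockout replicate 2. With no filter on signal no probe set was called, Taf7l included, and the smallest adjusted p was 0.065.

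Among called probe sets with a gene name, those that rose most in the knockout testis were for Cryl1, which encodes a lambda-crystallin-related dehydrogenase, and Nmnat3, an enzyme of NAD synthesis. Cryl1 went from 266 ± 18.2 to 2803 ± 993, a 10.2-fold rise (log2 3.35, SE 0.24, limma adjusted p = 0.024), and Nmnat3 from 317 ± 6.96 to 2416 ± 196, a 7.60-fold rise (log2 2.93, SE 0.087, limma adjusted p = 0.0033). The Nmnat3 rise was seen by 2 probe sets (3.60-fold at the other), whereas the other 2 Cryl1 probe sets, with signals near 87, differed by −0.09 and 0.00 on the log2 scale. Smaller rises were called for the potassium-chloride cotransporter gene Slc12a7 (3.41-fold), the heparan sulfate polymerase gene Ext1 (3.40-fold), the phosphoinositide 3-kinase subunit gene Pik3cd (3.61-fold, at 1 of its 3 probe sets), Depp1 (3.18-fold), the lipid droplet gene Fitm1 (3.09-fold), Bpifb3 (2.99-fold), the small GTPase gene Rab6b (2.78-fold) and the uncharacterised 4930447A16Rik (4.10-fold). Rises were also called for Gm31336 (27.6 ± 6.96 to 145 ± 2.57) and for Slc16a12 of the monocarboxylate transporter family (wild type mean 23.8, knockout mean 89.0), but their wild type signals lie under 45.8, the lowest mean kept, where signal is mostly background, so the size of the rise is not given as a fold. In all, 17 called probe sets had 1 group mean under that level.

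Among called probe sets with a gene name, the largest fall after that of Taf7l was that of Fscn1, an actin-bundling protein. It fell from 772 ± 32.3 to 168 ± 15.2, 4.61-fold lower (log2 −2.21, SE 0.10, limma adjusted p = 0.016). The other 2 kept Fscn1 probe sets, with wild type means of 83.7 and 127, differed by −0.22 and −0.27 and were not called. Ppargc1a, a coactivator of mitochondrial genes, was 2.87-fold lower at 1 probe set (153 ± 15.0 to 53.3 ± 1.65) and lower at the other 2, of which 1 was called, with a knockout mean of 37.3 that is also under 45.8. Falls were also called for the RNA-binding protein gene Larp6 (2.88-fold), the photoreceptor cilium gene Pcare (2.76-fold), the Polycomb-related gene Sfmbt2 (2.67-fold, from 2119 ± 4.31 to 796 ± 65.5), the scavenger receptor gene Msr1 (2.63-fold at 1 of its 3 probe sets, with 1.63-fold and an adjusted p = 0.051 at another and a difference of 0.03 at the dimmest), the cell polarity gene Patj (2.60-fold), the secretory granule gene Chgb (2.60-fold), and Tent5b (2.44-fold). Falls to a knockout mean under 45.8, and so of unknown size, were called for the prolactin family gene Prl3c1 (104 to 42.7) and the transcriptional coactivator gene Eya4 (72.9 to 31.1). A far brighter Eya4 probe set, at 2621 ± 12.7 and 2843 ± 96.1, differed by 0.12 in the other direction and was not called.

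**Figure D1:**
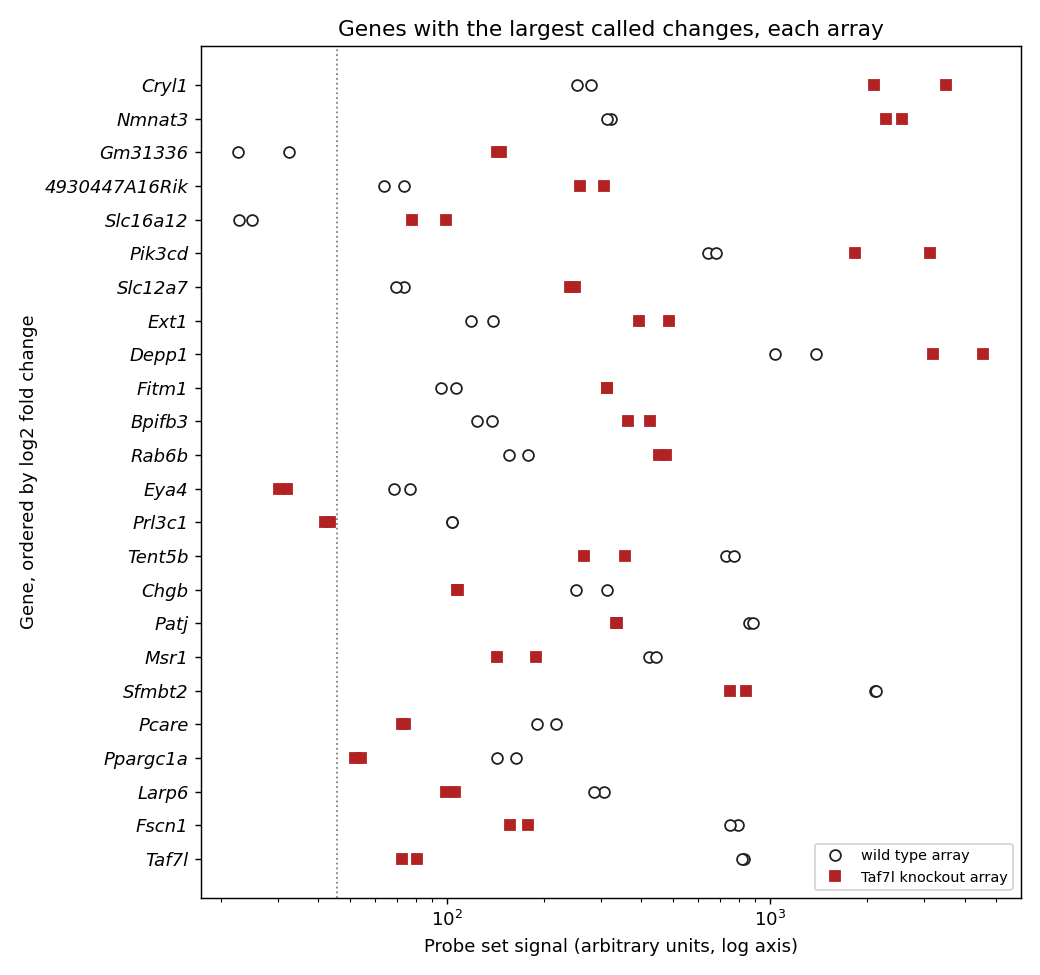
Probe set signal on each of the 4 arrays (arbitrary units, log axis) for the 12 genes with the largest called change in each direction, ordered by log2 fold change. Open circles are wild type arrays, filled squares are Taf7l knockout arrays and the dotted line is the lowest mean signal kept (45.8). Cryl1 lies at 253 and 279 in wild type and at 3505 and 2102 in the knockout, and Taf7l at 829 and 818 against 80.6 and 72.5.

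In all, 312 probe sets were called by limma, 100 higher and 212 lower in the knockout, which belong to 82 and 177 named genes. Of these, 45 were at least 2-fold higher and 24 at least 2-fold lower. Without a test, 107 kept probe sets were at least 2-fold apart with no overlap of the groups, 72 higher and 35 lower, and 69 of them were among the calls. Groups did not overlap in 55.0% of the kept probe sets, where chance gives 33.3%. The share of calls that were higher depended on the scaling, at 32.1% as deposited, 40.6% (283 of 697) with each array centred on its median, and 61.5% (91 of 148) after quantile normalization. The count itself was 0 with no filter (6192 probe sets at an unadjusted p under 0.05), 2375 with the 75th percentile filter, 36 without the variance trend, 806 with 1 probe set per gene, 179 with single-transcript probe sets, 2628 at an adjusted p under 0.10, and 0 with any 1 array left out, when limma gave 3084 probe sets at an unadjusted p under 0.05 without wild type replicate 1, 3544 without wild type replicate 2, 4639 without knockout replicate 1 and 5500 without knockout replicate 2. The count of probe sets 2-fold apart was 30 with the 75th percentile filter and 174 without knockout replicate 2.

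Some lists of late spermatogenesis genes were lower in the knockout, by small amounts spread over many members, counting each gene at its brightest probe set. Of 32 measured genes of the acrosome and fertilization, 31 were lower (median log2 −0.25, adjusted p = 6.4e-05). At these brightest probe sets, 0 of 32 passed the limma test over all genes, and 10 fell when adjusted over the list alone. The zymogen gene Acr was at 4017 ± 186 and 2836 ± 340 and Acrbp, whose product binds proacrosin, at 6765 ± 18.6 and 5308 ± 284. At the dimmer of their 2 probe sets, falls were called for Acrbp (1.506-fold, adjusted p = 0.049) and, chosen after its values were seen, Spesp1 (1.54-fold). Of 40 genes of the sperm flagellum, 38 were lower (median −0.16, adjusted p = 5.4e-05). Of these, 2 fell in the test over all genes, the axonemal dynein gene Dnaic2 (1.72-fold, with −0.02 at a dimmer probe set that was not called) and the testis-specific kinase gene Tssk3 (1.29-fold), and 13 fell when adjusted over the list alone. Among 38 genes of the manchette, sperm head and spermatid actin, 31 were lower (median −0.16, adjusted p = 0.00077). Fscn1 and the cylicin gene Cylc1 (1.60-fold) fell in the test over all genes, as did Clip1 at 1 of its 5 probe sets, not the brightest (1.57-fold, chosen after its values were seen), and 15 fell at the brightest ones when adjusted over the list alone. With an estimated correlation, none of the 9 lists called here and in what follows kept its call, and each had an adjusted p = 0.468. By fry only the manchette list kept it (adjusted p = 0.049), and not once Taf7l was left out of the TFIID list, which shares the adjustment (0.054).

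Genes active from pachytene spermatocytes onward were also lower as a list. Of 21 measured, 18 were lower (median −0.27, adjusted p = 0.0074), 1 fell over all genes, the calreticulin-family chaperone gene Calr3 (1.505-fold), and 10 fell when adjusted over the list alone. Pttg1, chosen after its values were seen, fell 1.56-fold at 1 of its 3 probe sets, not the brightest. Hspa2, the meiotic heat shock protein gene, was at 17934 ± 315 and 14083 ± 474 without passing. The list's adjusted p was 0.068 with the 75th percentile filter and 0.060 without wild type replicate 1. Of 20 genes of the CREM programme, the cAMP-responsive transcription of spermatids, 18 were lower (median −0.13, adjusted p = 0.044), with 0 passing over all genes and 2 falling when adjusted over the list alone. This call was lost under quantile normalization (adjusted p = 0.288), median centring (0.154), the 75th percentile filter (0.245), the mean of probe sets (0.147), single-transcript probe sets (0.212), and without wild type replicate 1 (0.159), knockout replicate 1 (0.085) or knockout replicate 2 (0.055). Among 18 sex chromosome genes of spermatids, 16 were lower (median −0.24, adjusted p = 0.00076). Cypt3 (1.48-fold) and Cylc1 fell over all genes, and 9 fell when adjusted over the list alone.

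Other germ cell lists were not called. The 19 genes of spermatid chromatin condensation had a median of −0.13 (adjusted p = 0.084), 16 of them lower, with the transition protein gene Tnp1 at 93154 ± 3040 and 83065 ± 2470. The 24 genes of sperm energy metabolism had a median of −0.11 (adjusted p = 0.062), which passed without wild type replicate 2 (0.031), and the 10 sperm ion channel genes −0.19 (adjusted p = 0.24), with Catsper1 at 1514 ± 35.4 and 1120 ± 54.1. Of 23 meiotic prophase genes, 12 were higher and 11 lower (median 0.02, mean −0.01, adjusted p = 0.72), of 12 spermatogonial markers 7 were higher (median 0.06, adjusted p = 0.36), and of 16 piRNA pathway genes 11 were lower (median −0.05, adjusted p = 0.99, the test pointing higher because other genes were lower still). The 23 measured genes of the retrogene list, not all of them retrogenes, had a median of −0.11 (adjusted p = 0.42). Of 26 TFIID and core promoter genes, 19 were lower (median −0.09, adjusted p = 0.17), and the median was 0.01 after quantile normalization. The list holds Taf7l itself, without which camera gave an adjusted p = 0.32. Of the 26, 2 fell over all genes, Taf7l and the TFIIF subunit gene Gtf2f2 (1.37-fold), and 4 when adjusted over the list alone. The TFIID subunit gene Taf5, at 242 ± 14.9 and 145 ± 9.88, had an adjusted p = 0.051.

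The Sertoli, Leydig and leukocyte lists were higher in the knockout, and other somatic lists were not called. Of 23 Sertoli cell markers, 15 were higher (median 0.07, adjusted p = 0.0043). Ptgds, a prostaglandin D synthase gene, rose 1.44-fold over all genes, 2 genes rose when adjusted over the list alone, and the protease gene Ctsl was at 13515 ± 611 and 18388 ± 1046. Of 14 Leydig cell markers, 9 were higher (median 0.12, adjusted p = 0.021). The steroidogenic gene Cyp17a1 rose 1.26-fold and 3 genes rose when adjusted over the list alone. Without knockout replicate 2 the Sertoli and Leydig lists had adjusted p of 0.055 and 0.061. Of 15 macrophage and leukocyte markers, 14 were higher (median 0.13, adjusted p = 0.00077), with 0 passing over all genes or over the list alone. The complement gene C1qb was at 881 ± 38.1 and 1089 ± 7.0 and the class II gene H2-Aa at 174 ± 29.4 and 281 ± 10.02. Markers of peritubular myoid cells (7 of 9 higher, median 0.07, adjusted p = 0.13) and of endothelium (4 of 7 higher, median 0.01, adjusted p = 0.32) were not called. Nor were those of fibroblasts (5 of 11 higher, median −0.08, mean 0.04, adjusted p = 0.32), although Col5a1, a collagen gene, rose 2.06-fold at 1 probe set (its other, not called, differed by 0.22). The ratio of 3′ to 5′ signal of the actin control, a sign of RNA integrity, moved with genotype as these lists and the lower germ cell lists did. It was 2.09 and 1.999 on the wild type arrays and 2.42 and 2.18 on the knockout arrays, while that of Gapdh was 1.04 and 0.990 against 0.927 and 0.938. Without wild type replicate 2 the fibroblast median was 0.04 and the endothelial median −0.07.

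Some adipocyte and epididymis markers differed between arrays of 1 genotype. Of the genes named here, Car3, Fabp4, Lpl, Defb15, Adam7, Lcn5 and Spink8 fall outside the naming rule and were chosen after their values were seen. Spink8 is on no list. An unnamed probe set had a signal of 1804 on wild type replicate 2 and 11.7, 9.58 and 9.04 on the other 3 (limma adjusted p = 0.35 between genotypes, not called), and Spink8 had 150 against 17.3, 10.1 and 12.7. Among adipocyte genes, 9 of 11 measured were higher on that array than on wild type replicate 1, Car3 11.8-fold, Fabp4 8.56-fold and Lpl 4.86-fold, and among epididymis markers 5 of 7, Cuzd1 2.27-fold. Knockout replicate 2 also had more Fabp4 (552) and Car3 (535) than wild type replicate 1 (170 and 124) and knockout replicate 1 (264.5 and 275). Of the 7 epididymis markers kept by the filter, Cuzd1 and Defb15 were highest on wild type replicate 2 among the 4 arrays, while Lcn2 (15416 against 9391) and Sult1e1 (1018 against 611) were higher on knockout replicate 2. Under the filter, Adam7 had 23.6 on wild type replicate 2 against 8.59 at most, and Lcn5 21.7 against 21.1 at most. Signals that low are mostly background, so these ranks are not read. The adipocyte list had a median of −0.32 (8 of 11 lower, adjusted p = 0.65), −0.62 without wild type replicate 1 (adjusted p = 0.014) and 0.17 without wild type replicate 2 (adjusted p = 0.17). The epididymis list had a median of 0.05 (6 of 7 higher, adjusted p = 0.24). Of the red blood cell list only 1 gene was measured, Alas2, at 173 ± 23.7 and 141 ± 6.24. The 15 immediate early and heat shock genes had a median of 0.07 (adjusted p = 0.24), and Jund fell 1.504-fold. The 15 apoptosis and p53 target genes had a median of −0.02, which was 0.04 after quantile normalization (adjusted p = 0.13, and 0.0041 without knockout replicate 1), and Pmaip1, which encodes the BH3-only protein Noxa, rose 1.74-fold.

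**Figure D2:**
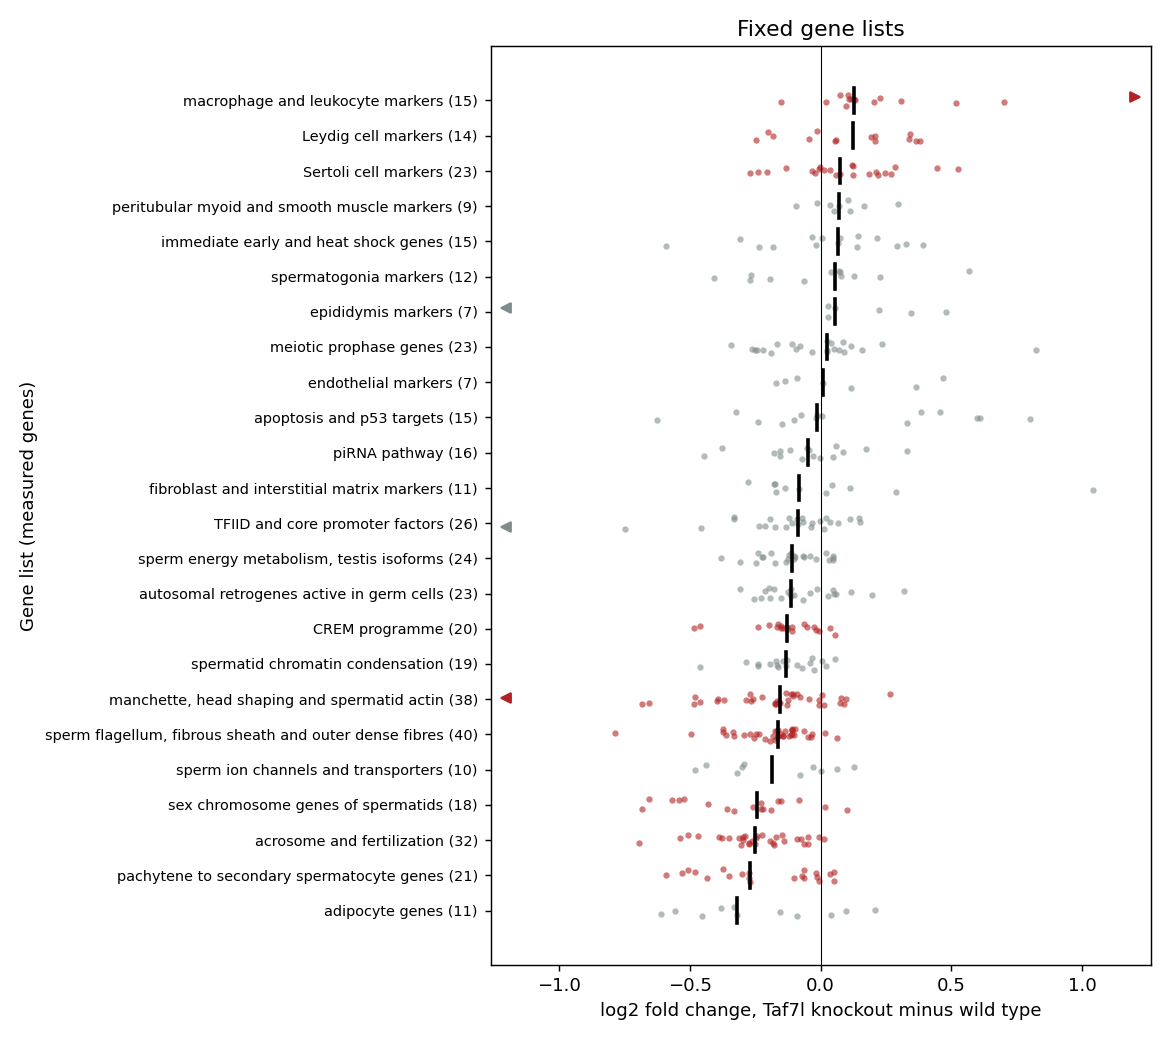
Log2 fold change (Taf7l knockout minus wild type) of each measured gene on the 24 tested lists, 1 point per gene at its brightest probe set, with a black bar at the list median and arrowheads for genes beyond the axis. The 9 lists called by camera are red, and the acrosome list has 31 of 32 points below 0.

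X-linked genes were not shifted as a set but were frequent among those that fell. The 370 measured X-linked genes had a median log2 difference of −0.04 and were not called by camera (adjusted p = 0.80, equal to the raw p for a single test), and the median was 0.00 after median centring. Of them, 18 fell (4.86%), against 158 of 11793 autosomal genes (1.34%), an odds ratio of 3.77 (95% interval 2.15 to 6.23, Fisher's exact test, two-sided, p = 6.8e-06, adjusted p = 2.0e-05 over 3 such tests), and 0 rose, against 81 autosomal genes (exact p = 0.18). Besides Taf7l they included the spermatid genes Cylc1, Cypt3 and, chosen after their values were seen, the histone variant gene H2al3 (1.97-fold), the ubiquitin ligase scaffold gene Cul4b (1.48-fold, while a dimmer probe set was 0.31 higher on the log2 scale and not called) and the retinal ciliary gene Rpgr (1.62-fold). Without the variance trend the odds ratio was 3.19, but only 11 probe sets fell in all, 1 X-linked gene among them, and the exact test did not pass (p = 0.29). At an adjusted p under 0.10 the odds ratio was 1.26 (exact p = 0.13), with 57 lower and 9 higher. It passed at a smaller size with median centring (2.29, with 22 lower and 3 higher), the 75th percentile filter (1.90, with 55 and 4) and 1 probe set per gene (2.10, with 35 and 3), and at a larger one after quantile normalization (5.27, with 7 and 0).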

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

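The tests in this part were not planned and were set after the array values had been seen. Among the mouse control probe sets, which entered no comparison, those for Gapdh were higher on both knockout arrays than on both wild type arrays, by 0.34 on the log2 scale at the 3′ end, 0.46 at the 5′ end and 0.26 in the middle. They were flagged because that gap exceeded the gap between arrays of 1 genotype. The middle probe set of the transferrin receptor was higher by 0.13, but its signals of 22.0 to 24.7 lie under 45.8, where signal is mostly background. All 4 stayed higher with median centring (Gapdh 0.39, 0.51 and 0.31, transferrin receptor 0.18) and after quantile normalization (Gapdh 0.47, 0.59 and 0.39, transferrin receptor 0.12). Some spike-in controls met the same gap the other way. They were lower on the knockout arrays by 0.23 (bioC), 0.20 and 0.18 (bioB). The differences were 0.19, 0.16 and 0.14 with median centring and 0.13, 0.17 and 0.15 after quantile normalization. All bioB, bioC and bioD probe sets had a lower mean on the knockout arrays, by log2 differences from −0.05 to −0.35, while those for cre ran from −0.07 to 0.03. These controls are not mouse transcripts, so differences of this size between the groups can arise from the handling of the arrays or from scaling. This limits the reading of small changes, the list medians among them. The scaling of the arrays stays unsettled. On the mouse 18S ribosomal RNA control, knockout replicate 1 stood apart at the 5′ end. It had 689, against 398 and 372 on the wild type arrays and 397 on knockout replicate 2. What set that array apart was not tested. No biological explanation of these values was tested.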

How the results depend on the processing

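The single-transcript probe sets for lists and for 2-fold counts, the TFIID list without Taf7l, and every alternative for the odds ratio of X-linked genes, were chosen after seeing the data. All 312 calls kept their sign after quantile normalization and median centring, the only alternatives that could have changed it. In every called probe set the groups did not overlap, so the offset and leaving out an array could not reverse a sign. The other alternatives left the log2 difference as it was. The count of 312 became 148 after quantile normalization (137 of the 312 still called), 697 with median centring, 0 with no filter, 2375 with the 75th percentile filter, 36 without the trend, 541 with the replicate block, 2628 at an adjusted p under 0.10, 179 with single-transcript probe sets, 806 with 1 probe set per gene, and 0 with any 1 array left out. It was 305 with the offset and 217 with the robust prior. The 75th percentile filter, single-transcript probe sets and 1 probe set per gene test fewer probe sets, and no filter tests more. Leave-one-out fits have fewer arrays. The number tested does not set the count alone, since single-transcript probe sets gave fewer calls with fewer tests. The prior degrees of freedom also moved, from 3.17 to 6.22 with the 75th percentile filter and to 1.92 with no filter. Why each count moved was not tested. The replicate block rests on numbers that the labels do not tie to litters or days. Deviations of same-numbered arrays correlated at 0.032 (Pearson) and −0.0049 (Spearman) across probe sets. The arrays numbered 2 held the same value at 2385 probe sets, against 229 to 620 for the other pairs. What same-numbered arrays share is therefore not settled.

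Of the 34 called probe sets of named genes besides Taf7l, 34 kept their call with median centring, 33 with the offset, 33 with the block, 26 with quantile normalization, 26 with the robust prior, 17 without the trend and 0 with any array left out. Taf7l stayed called with quantile normalization, median centring, the offset, no trend, the robust prior and the block. It was not called with no filter, where the smallest adjusted p of any probe set was 0.065, nor in the leave-one-out fits, which gave −3.51 to −3.35. Probe sets 2-fold apart numbered 107, 30 with the 75th percentile filter, and 133 to 174 with 1 array left out. Called lists numbered 9, 0 with an estimated correlation and 2 with fry (TFIID at an adjusted p of 0.017 and manchette at 0.049), 6 to 11 otherwise. The TFIID list holds Taf7l; without it fry called 0 lists (TFIID and manchette at 0.054) and camera the same 9. The median of X-linked genes changed sign with median centring (0.0028), and their odds ratio was 3.19 without the trend and 1.26 at an adjusted p under 0.10, between 1.90 and 5.27 in the other settings run for it. With no filter or 1 array left out nothing was called, so no odds ratio exists.

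Some results that had not been called changed direction. Tbp became 0.045 after quantile normalization. With 1 array left out, Rnase10 ranged from −0.0027 to 0.45, Taf7 from −0.32 to 0.013 and the adipocyte list from −0.62 to 0.17. The test of the piRNA list changed direction with no filter (median −0.053), the block (−0.049), the mean of probe sets (−0.058), fry (−0.049) and without wild type replicate 1 or knockout replicate 2 (−0.056 to −8.6e-06 over the 4 arrays left out in turn), and that of the meiotic prophase list with single-transcript probe sets (−0.055), fry (0.023) and without knockout replicate 2 (−0.078 to 0.022 over the 4). The causes were not tested. Probe sets with a mean signal under 45.8 were not tested, and a change in them was not looked for outside the setting with no filter.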

Other observations

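Some further transcripts, chosen after their values were seen, moved in ways the lists did not cover. Azin2, which encodes an antizyme inhibitor of the polyamine pathway, fell from 3376 ± 56.4 to 1560 ± 53.1 (log2 −1.11, limma adjusted p = 0.023), while the 2 bright probe sets of the testis antizyme gene Oaz3 differed by 0.06 and 0.00 and another, dim one was 2.03-fold higher without passing (45.9 ± 8.07 to 92.6 ± 6.76, adjusted p = 0.051). The keratin gene Krt8 rose at 2 of its 3 probe sets, 1.99-fold at the brighter (255 ± 36.0 to 507 ± 31.8, limma adjusted p = 0.048), and differed by 0.76 at the dimmest, which did not pass. The probe set assigned to H2-Ea rose 2.19-fold (120 ± 1.34 to 265 ± 37.2) and that of the lysosomal glucuronidase gene Gusb 2.04-fold (62.8 ± 0.50 to 128 ± 7.32). The adjusted p was 0.047 for H2-Ea and 0.043 for Gusb by limma.

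The tests that follow were chosen after the results they bear on had been seen, except the count of splits of the arrays, and the separation of the called lists into 7 and 2 was also made afterwards. Of the 9 called lists, those of germ cells were lower and those of somatic cells higher, while other lists of both kinds were not called. A brightness trend is a technical candidate, since the kept probe sets at or above the 75th percentile of signal had a median of −0.09 against −0.01 in the others. Of the 9 called lists, 7 lay outside the central 95% of random lists matched on signal, and 0 of the other 2 did (manchette at percentile 7.43 and CREM at 17.4). Brightness or scaling may account for those 2. When the arrays were rescaled by quantile normalization or by median centring, 8 lists were called each time, 5 of them lower. Of the 2, CREM lost its call under both, as given above. Random genes as bright as the other 7 lists rarely gave such medians. However, these lists had been called from the same values, and random lists ignore correlation between genes. Some lists that were not called lay outside too: meiotic prophase at percentile 99.5, immediate early and heat shock genes at 98.9 and adipocyte genes at 0.14. A lower share of late germ cells in the knockout testis would raise all somatic lists alike. The 6 somatic medians, from −0.11 to 0.13, were no further apart than permuted members (permutation p = 0.2). With only 7 to 23 genes per list, this does not show that the lists moved alike. Their pooled median of 0.07 lay at percentile 100 of matched random lists. However, 23, 14 and 15 of its 77 members came from the Sertoli, Leydig and leukocyte lists, already called higher from the same values. The fibroblast median was −0.11 here (members on 2 somatic lists left out) and 0.04 on its whole list without wild type replicate 2, so a change in cell shares and a change within cells cannot be told apart.

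The X-linked genes that fell were not only the brighter ones: over 10 brightness bins and without Taf7l, the common odds ratio was 5.13 (95% interval 2.84 to 8.77). DNA of another strain around the targeted gene could also lower X-linked signals. Of the 40 measured X-linked genes nearest Taf7l, 4 fell (odds ratio 2.69, 95% interval 0.61 to 9.33, Fisher's exact p = 0.099). That interval spans both outcomes, so linked strain DNA and a genotype effect cannot be told apart for these genes. A lower share of late germ cells, raised above for the lists, was not tested for X-linked genes. Those that fell included the spermatid genes Cylc1, Cypt3 and H2al3, and the list of sex chromosome genes of spermatids was itself lower.

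Many 2-fold changes were seen at 1 probe set of a gene and not at its others. In 38 genes with another kept probe set, the median ratio of the other probe sets' change to the 2-fold one was 0.149 (bootstrap 95% interval 0.039 to 0.259), with 27 in the same direction and 3 with a ratio of at least 0.5. This is consistent with changes in part of a transcript, or at the probes themselves, for those genes as a set, Cryl1 and Pik3cd among them, though the lead probe set was picked for its size and other probe sets were often dim. Blocks of DNA from another strain would group such genes along chromosomes: 14 of 91 had another within 10 measured genes, where random draws gave a median of 12 (95% range 4 to 21), so this explanation and a genotype effect cannot be told apart. As for chance, the 4 arrays allow only 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 312 calls and the highest other 0. Each other split mixes the genotypes, so any difference between them widens its spread and lowers its calls. No conclusion about chance is drawn from that 0.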
